A study of Drosophila melanogaster with 12 samples.

How the data were processed

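DamID-seq marks where a protein sits on the genome. The protein is fused to the bacterial Dam methylase, which methylates adenines in nearby GATC sites, and the methylated fragments are amplified and sequenced. Dam on its own marks open chromatin and serves as the background. Here the protein was Doublesex (DSX), a Drosophila transcription factor made in a female form (DSX-F) and a male form (DSX-M). Per the labels, flies carried 1 transgene for Dam, Dam-DSX-F or Dam-DSX-M, inserted at the same landing site on chromosome arm 3L, and tissue was dissected at 5 days of age. The 12 samples fall into 6 groups of 2 biological replicates. These are Dam alone and Dam-DSX-F in female fat body, Dam alone and Dam-DSX-M in male fat body, and Dam alone and Dam-DSX-F in ovary.

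Per the submitters' processing notes, the tools used upstream were CASAVA 1.8.0, Bowtie 0.12.7, Picard, HTSeq 0.5.1p2, DESeq 1.12 and bedtools 2.16.2, with the dm3 genome build. The notes give no role or order for these tools. The deposited signal values are mean normalised read counts per 500 bp window and group, per the file headers, for 279473 windows in each of 3 tables. The deposited log2 fold changes compare condition B with condition A, and the deposited p-values, raw and adjusted, belong to that comparison, per the file headers. The headers name the conditions only A and B. A was read as Dam and B as the fusion, because the authors' peaks lie where B is above A, and every direction below rests on that reading. Peak lists hold positions only, with no score. Per the labels, peaks were called from both replicates together, so each tissue and sex has 1 list.

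The deposited means are sums of whole reads divided by size factors, so the reads of each library were recovered. Each mean was solved for the whole numbers of reads in 2 libraries. In all 6 groups 100% of windows had exactly 1 solution within a tolerance of 1e-06 of a read step. On simulated tables the lowest share of windows recovered exactly was 100%. Median-of-ratios size factors computed over 8 fat body libraries and over 4 ovary libraries matched the steps, with a difference of 0%. The 2 fat body tables were thus scaled together and the ovary table separately. Recovered libraries carry no replicate numbers and are called a and b within a group. Depth is given as recovered reads in windows. A count of 0 allows up to 3 counts. A floor takes the reads of the other group as measured, so it is not a 95% limit and can exceed the lower end of a counting interval. Counting intervals are 95% Clopper-Pearson intervals on reads pooled over both libraries of a group. Pooling weights libraries by depth, so an interval is not centred on the ratio of the deposited means. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Largest windows reached 917 reads in ovary libraries, and 11962 windows exceeded 500 reads in ovary fusion library a against 19 in female fat body Dam library a.

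Windows were counted at a deposited adjusted p under 0.05, for each direction. A window with no read in any library of a table has no p. Standard errors of log2 fold changes were back-calculated as the size of the log2 fold change over the normal quantile of the deposited p. Differences between tissues were tested as the difference of log2 fold changes with those errors, by a normal test with Benjamini-Hochberg adjustment. Windows without a read in 1 of the 4 groups have no finite fold and were left out of this test. Windows whose deposited p gave no finite standard error stayed in the test and were counted as not differing. On simulated values with 200 windows shifted by 2 on the log2 scale, this test recovered 156 and made 7 false calls among 50000. All simulated windows had the same standard error, smaller than every fat body standard error given below. That recovery therefore does not carry over to these data. Peak lists were compared by overlap of at least 1 bp (bedtools 2.31.1), against 1000 shuffles of the second list over the tested windows of each chromosome, with a 2-sided permutation p. The smallest p that 1000 shuffles can give is 0.002. Expected overlap was also computed within chromosomes and deciles of read level, taken from the Dam and fusion means of both tissues. Profiles were correlated over windows with a mean of at least 10 in both tables, against 1000 circular shifts within chromosomes. Medians by chromosome were taken over windows with a mean of at least 10 and carry the SD of 200 bootstrap draws of 100 kb blocks. Matching by read level was chosen after the overlaps were seen.

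Scaling by total reads, the edgeR interaction tests with their leave-out fits, the fits with a replicate block, and the rebuilt ovary list were chosen after seeing the data. As alternatives, the recovered reads, 100% of windows, were fitted with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 in R 4.3.3. Fits in edgeR used TMM scaling, scaling by total reads, and each library left out. DESeq2 was fitted on all libraries of a tissue, with its own size factors and default filter. It left 56825 windows of male fat body without an adjusted p. In edgeR simulations of female fat body with 238321 windows, 63 of 100 windows changed 4-fold were recovered and 0 of 100 changed 2-fold, with 3 false calls. All windows had the same dispersion, and few were changed, while edgeR called far more in the real data. An adjusted p is easier to pass where many windows change, so this recovery does not carry over to the counts within tissues. In the interaction simulation, 19 of 100 windows changed 4-fold and 0 of 100 changed 2-fold were recovered, with 2 false calls over 246175 windows. Other alternatives were a threshold of 0.01, a mean of at least 10 or 30, a log2 fold change of at least 1, chromosome arms only, reciprocal overlap of at least 50%, a distance of up to 500 bp, and the 50% of peaks with larger folds. Python was 3.11.15, with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

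The rule for named places was fixed before the data were examined, as were the main tests and most alternatives. It takes, on arms X, 2L, 2R, 3L, 3R and 4, the 15 peaks per list with the largest deposited log2 fold change of a window, 10 regions of all 3 lists by their lowest rank, and 5 windows per direction of each difference test, with neighbours within 2 kb counted once. A rank was taken as a share of its list's length. Within a region of all 3 lists, the window shown is the one called higher in all 3 tables with the highest lowest-of-3 log2 fold change, and that choice of window was made after values were seen. Places are named by dm3 coordinates. An annotation or sequence of dm3 was not used here, so no place is assigned to a gene, and the 15 gene lists, the DSX motif and distances to transcription starts, planned beforehand, were not analysed here. Fold changes of the named genes in the rule and of the landing site were not analysed here for the same reason, and windows in the dsx gene, which the transgene also carries, could not be set apart.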

Results

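Genomic occupancy of the Doublesex (DSX) transcription factor was profiled by DamID-seq in adult fat body of both sexes and in ovary of Drosophila melanogaster. The fat body is the fly's main metabolic and storage organ. The female form, DSX-F, was profiled in female fat body and ovary, and the male form, DSX-M, in male fat body, each against Dam alone in the same tissue. Every group held 2 libraries. Fat body libraries held 7727943 to 13774211 recovered reads in windows, and ovary libraries 20987350 to 38580572. Reads of replicate libraries varied 2.42 to 7.28 times as much as binomial sampling of windows with at least 20 reads would give.

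In female fat body, DSX-F occupancy was spread over all chromosome arms in short stretches. The fusion exceeded Dam in 34157 windows of 500 bp and fell below it in 30457, of 241814 tested, at a deposited adjusted p under 0.05. The authors' list held 10878 peaks covering 11.5 Mb, and 54.1% of them were a single window. Median log2 fold change in peak windows was 1.93 in the authors' deposited table. The longest peak spanned 12.5 kb at 2L 8691501 to 8704000, with mean normalised read counts of 92.7 for Dam and 369 for the fusion. Of the 15 peaks with the largest folds, 9 contained a leading window without a Dam read. The first of them, 2L 7608501 to 7609000, had 21 and 24 fusion reads and was at least 21.3-fold higher in the fusion, with the floor of 3 counts taken over the Dam group. Its counting interval started lower, at 16.3. A window at 3R 16069501 to 16070000 had 3 Dam reads and 106 and 68 fusion reads, a 79.8-fold ratio with a counting interval of 27.2 to 396. At 3L 16158001 to 16158500 the authors' deposited table gave a log2 fold change of 5.70 (SE 0.77), and this peak overlapped peaks of the other lists. There the log2 fold change was 2.86 (SE 0.76) in male fat body and 3.30 (SE 0.50) in ovary. None of the 15 leading peaks lay on the X. Calls in edgeR ended when either fusion library was left out, with 0 windows in both directions. Higher windows numbered 40415 and 42795 without Dam library a or b, and lower windows 38061 and 38670, against 48775 and 49571 with all libraries. At an unadjusted p under 0.05 those fits still held 48620 windows higher and 50193 lower without fusion library a, and 43135 and 43912 without fusion library b, while DESeq2 on all 4 libraries called 43934 higher and 31080 lower.

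In male fat body, DSX-M exceeded Dam in 26479 windows and fell below it in 22933, of 244247 tested, by the deposited adjusted p. DESeq2 on the recovered reads called 23768 higher and 11130 lower. Male counts in edgeR depended strongly on whether and how the libraries were fitted as pairs. The authors' list held 8909 peaks over 7.38 Mb, of which 66.0% were a single window. Median log2 fold change in peak windows of the authors' deposited table was 1.81. The longest peak, 10.5 kb at 2L 8691501 to 8702000, began at the same position as the longest female peak. Of the 15 leading peaks, 7 had a leading window without a Dam read, and these were ranked first. A female fat body peak overlapped 8 of the 15, against 72.4% of all male peaks, and 8 belonged to all 3 lists. At 2L 20041501 to 20042000 the male fusion libraries held 159 and 118 reads against 0 and 1 Dam reads, a 288-fold ratio with a counting interval of 64.6 to 14391. Female fat body held 1 fusion read in that window and ovary 16. At 3L 9413001 to 9413500, with 2 Dam reads in males, the male ratio was 120-fold with a counting interval of 39.1 to 1187. The log2 fold change there in the authors' deposited table was 4.17 (SE 0.63) in female fat body and 2.09 (SE 0.38) in ovary. At 2L 12506001 to 12506500 the mean normalised read count was 211 for the fusion against 3.93 for Dam in males, and 20.7 against 5.94 in females. X windows without a Dam read at 3265501 and 16825001 were at least 9.74-fold and 8.79-fold higher in the male fusion by the floor, and female fat body peaks covered both. Their male counting intervals started at 8.24 and 8.60. Higher windows in edgeR numbered 36055 with all libraries, 17067 and 13670 without Dam library a or b, and 26366 and 29634 without fusion library a or b. Lower windows numbered 33195, 7537, 8076, 23516 and 27406 in the same order.

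Direction counts in fat body depended on how libraries were scaled. Under edgeR's TMM scaling 49.6% of called windows were higher in the female fusion, against 27.1% under scaling by total reads. The male shares were 52.1% and 23.1%, and the deposited shares 52.9% in females and 53.6% in males. Scaling by total reads moved the median log2 fold change from -0.30 to -0.83 in females and from -0.29 to -0.82 in males. All folds here are relative to the deposited size factors.

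In ovary, DSX-F exceeded Dam in 25344 windows and fell below it in 34380, of 248228 tested, by the deposited adjusted p. Median log2 fold change of the windows called higher in the authors' deposited table was 1.27. Ovary libraries were deeper, which lets smaller folds pass the threshold, so this median is not set against those of fat body. The authors' ovary list held 13349 peaks over 14.6 Mb, and its longest peak spanned 18 kb at X 218001 to 236000. All 15 leading ovary peaks had a leading window without a Dam read. At 3L 2121501 to 2122000 the fusion libraries held 137 and 81 reads, at least 43.9-fold higher than Dam. Female fat body Dam libraries held 36 and 23 reads in that window and male ones 22 and 17. The 15 leading ovary peaks tied at an infinite fold and were ordered by fusion mean alone, so they need not stand for the list. None of the 15 overlapped a male fat body peak, against 34.7% of all ovary peaks. A female fat body peak overlapped 2 of the 15, against 42.7% of all ovary peaks. Among those overlapping, 3L 5904001 to 5904500 had no Dam read in either tissue. By the floor it was at least 20.8-fold higher in the ovary fusion and at least 19.2-fold higher in the female fat body fusion. The counting intervals there started at 25.5 and 15.2. The ovary list did not follow its own table, so its length cannot be compared with those of the fat body lists. Of its 29266 windows, 7786 had a deposited adjusted p of 0.05 or more, while both fat body lists were exactly the higher windows under 0.01. An ovary list rebuilt with the fat body rule held 7909 peaks. Higher ovary windows in edgeR numbered 31286 with all libraries, 9190 and 14066 without Dam library a or b, and 28882 and 14159 without fusion library a or b. Lower ovary windows numbered 32374, 7547, 2834, 38292 and 23840 in the same order.

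The peak lists of both fat bodies and the ovary had many places in common. Of the female fat body peaks, 5824 (53.5%) overlapped a male peak, where shuffles gave a mean of 1154 (SD 29.7). In the other direction 6450 male peaks (72.4%) overlapped a female one. Female fat body and ovary, which had the same DSX-F fusion, had 6082 overlapping female fat body peaks (55.9%), against 1999 (SD 40.5) by shuffling. Male fat body and ovary had 5405 overlapping male peaks (60.7%), against 1431 (SD 35.3). Each permutation p was 0.002, the smallest that 1000 shuffles give, and the direction was the same for all 3 pairs. Shuffled peaks could fall on any tested window, also those with too few reads for a call. Lists limited to well-covered windows can exceed such shuffles, so neither this p nor the shuffled means can show shared DSX binding. Shared windows exceeded the expectation by 7.47, 4.41 and 5.01 times for independent lists, in the order of pairs above. Within chromosomes and deciles of read level the excess was 2.45, 1.98 and 2.00 times. Read level joined Dam and fusion reads of both tissues, so it holds the fusion signal that defines a peak. The fall therefore cannot show how much of the overlap followed read level or chromosome. Merging all lists gave 17352 regions, and 3857 of them had a peak of every list, against a shuffled mean of 740 (SD 23.7). With an ovary list rebuilt from the deposited table at 0.01, 3359 female and 2898 male fat body peaks overlapped ovary peaks, against shuffled means of 1011 and 701, and 2620 regions had all 3.

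**Figure D1:**
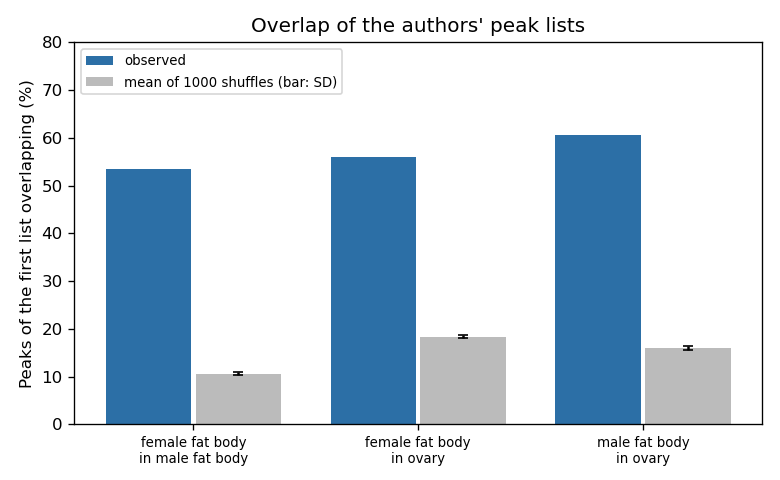
Share of peaks in the first list that overlap a peak of the second list, in percent, for the 3 pairs, with observed shares beside the mean of 1000 shuffles and its SD. The observed shares are 53.5%, 55.9% and 60.7%, against shuffled shares of 10.6%, 18.4% and 16.1%.

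The 10 leading regions of all 3 lists lay on X, 2L, 2R, 3L and 3R. Each of these 10 held a window called higher in all 3 tables. The first, 3R 16098501 to 16104500, had its leading window at 16099501, with log2 fold changes of 3.50 (SE 0.66) in female fat body, 2.57 (SE 0.68) in male fat body and 2.40 (SE 0.49) in ovary in the authors' deposited table. Of the 10, 3 lay on the X between 3334501 and 3669500. In the X region from 3567501 to 3577500 the window at 3570501 had log2 fold changes of 3.17, 2.71 and 2.42 in the same order. On 2L, a 9 kb region at 16492001 to 16501000 had Dam means of 23.8, 29.1 and 86.3 and fusion means of 210, 216 and 402 in its leading window. At 2R 4124501 to 4125000 the fusion was 15.2-fold higher in female fat body (counting interval 8.51 to 27.6) and 30.5-fold higher in male fat body, where Dam had 3 reads (7.80 to 120). In ovary it was 2.64-fold higher (1.92 to 3.32).

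**Figure D2:**
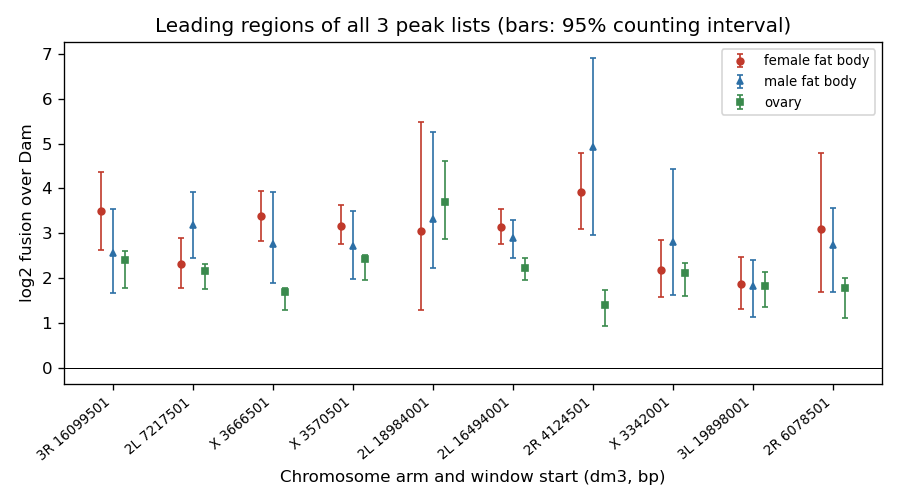
Log2 ratio of fusion over Dam in the leading window of the 10 leading regions shared by all 3 peak lists, from the authors' deposited table for each tissue, with 95% counting intervals as bars. All points lie above 0 because the windows shown were chosen as called higher in all 3 tables, and 2R 4124501 has the highest male value, 4.93.

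DSX-F and DSX-M profiles in fat body were strongly correlated. Across 155503 windows the log2 fold changes of female and male fat body had a Pearson r of 0.848 and a Spearman rho of 0.855, with a permutation p of 0.001 for each, the smallest that 1000 shifts give. The r between female fat body and ovary was 0.598 and between male fat body and ovary 0.562, with rho of 0.594 and 0.565 and the same permutation p. Windows are not independent replicates, and the largest shifted r was 0.139. Circular shifts break all positional features that tissues have in common, and r was not limited to chromosome arms or matched on read level. It thus measures likeness of fusion over Dam ratios, not of DSX binding alone. These 3 pairs were the whole family of correlations, so the adjusted p equals the raw one. Of 34659 windows called in both sexes, 34641 had the same sign and 18 the opposite one. The direct test found 34 windows of 212155 that differed between the sexes, 14 higher and 20 lower in females. Windows without a read in 1 of the groups have no finite fold and were not compared, such as 3R 16069501, with 0 fusion reads in males. Among compared windows 2L 20041501 had the largest difference, with a log2 difference of -10.31 (SE 1.92), female minus male, although it rests on 1 male Dam read and 1 female fusion read. Next was 3L 2423001 to 2423500, where males had 193 and 260 fusion reads against 3 and 9 Dam reads, and females 2 and 2 against 11 and 5, a difference of -6.98 (SE 1.14). At X 16588501 to 16589000 the log2 fold change was 3.54 in males and -2.03 in females. Among windows higher in females, 3L 3567001 to 3567500 had 64 and 49 fusion reads in females and 0 and 1 in males, with 38 and 31 Dam reads in females and 28 and 34 in males, a difference of 6.62 (SE 1.16). The female log2 fold change of 1.19 was not called (adjusted p 0.0884), so the difference came mainly from the male value of -5.43. The male ratio of fusion over Dam had a counting interval of 0.000527 to 0.122. At 3L 5240501 to 5241000 the log2 fold change was 1.96 in females and -2.91 in males. An interaction test in edgeR called 26 windows, 22 of them among the 34, and held 17359 at an unadjusted p under 0.05. It called 626 under scaling by total reads, of which 22.7% were higher in females against 41.2% in the main test. The count fell to 0 without female fusion library a, without male Dam library a or without male Dam library b, and to 2 without female fusion library b. At an unadjusted p under 0.05 those fits held 15041, 15831, 12384 and 12114 windows in that order. The count rose to 103 and 72 without female Dam library a or b, and to 608 and 878 without male fusion library a or b. The count also depended on whether and how the libraries were fitted as pairs, and was far higher for 1 of the 2 ways to pair the male libraries, the one that their deviations favour, so 34 is not an upper limit. In simulation the edgeR interaction did not recover 2-fold differences.

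Female fat body and ovary, which both had the DSX-F fusion, differed in more called windows than the sexes did. The test of the difference called 14172 of 220987 windows, 11074 higher and 3098 lower in fat body. These tables were scaled separately and ovary libraries were deeper, so this count is not comparable with the 34 windows between the sexes. At an unadjusted p under 0.05 the edgeR interaction held 74039 windows here, against 17359 between the sexes. Largest windows reached 917, 916, 917 and 917 reads in the ovary libraries. The ovary fusions had 11962 and 10727 windows above 500 reads, against 1461 and 1551 in the female fat body fusions. A ceiling on reads per window, which could compress ovary ratios in deep windows, was not tested for this comparison. The split followed the scaling. Under scaling by total reads, edgeR's interaction called 43197 windows with 33.0% higher in fat body, against 78.1% in the main test and 65.8% with TMM. The edgeR count with TMM was 35385 with all libraries. Without female Dam library a or b it was 13561 and 24998, and without female fusion library a or b 29980 and 10090. Without ovary Dam library a or b it was 20794 and 5508, and without ovary fusion library a or b 41510 and 37515. At 2L 4587001 to 4587500 the fusion mean was 159 against 18.2 for Dam in female fat body and 1.82 against 57.0 in ovary, a log2 difference of 8.09 (SE 0.97). The male fat body log2 fold change there was 1.91 (SE 0.52). In the opposite direction, 3L 124001 to 124500 had a fusion mean of 2.69 against 175 for Dam in female fat body and 116 against 54.8 in ovary, a difference of -7.11 (SE 0.74). Male fat body went with female fat body there, with 7.39 against 123. Of 26263 windows called in both tissues, 97.0% had the same sign.

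Peak shares and ratios of fusion over Dam also differed by chromosome. On the X, 8.22% of tested windows lay in male peaks, against 6.19% on the autosomal arms, while in females the shares were 8.97% and 10.5%. Median log2 fold change on the X was 0.53 (bootstrap SD 0.04) in males and 0.10 (SD 0.04) in females, and on autosomal arms 0.10 and 0.15 (SD 0.02 for each). Chromosome medians cover only windows with a mean of at least 10, while the percentages cover all tested windows. That filter kept 25028 of 40900 tested X windows in males and 28430 of 41557 in females, so the X medians of the sexes cover different windows. Over X windows that passed in both sexes, the median female minus male difference was -0.33. Male Dam libraries had 11.1% and 10.5% of their reads on the X and male fusion libraries 13.2% and 12.5%. Female fat body libraries had 16.7% to 16.9% and ovary libraries 17.1% to 17.4%, so the X share was lower in all 4 libraries labelled male. Chromosome 4 had a median log2 fold change of 0.57 (SD 0.03) in ovary, -0.11 (SD 0.06) in female fat body and -0.18 (SD 0.10) in male fat body. The heterochromatic Het arms were low in the fat body fusions, with 24.1% of their tested windows called lower in females and 24.8% in males, against 9.23% in ovary. Of these arms XHet was an exception, with a median log2 fold change of 0.22 in males, -0.10 in females and 0.34 in ovary, and with 6.64% of its windows called higher and 5.47% lower in males, but 3.89% higher and 7.78% lower in females. Reads of all Het arms fell from 1.63% and 1.47% in female Dam libraries to 0.61% and 0.50% in the fusions, and from 1.72% and 1.95% to 0.59% and 0.63% in males. Ovary Dam libraries had 1.08% and 0.98% there and ovary fusions 0.85% and 0.85%. With 2 libraries against 2, an exact 2-sided permutation test cannot give a p below 0.333, so these library shares are given without a p.

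**Figure D3:**
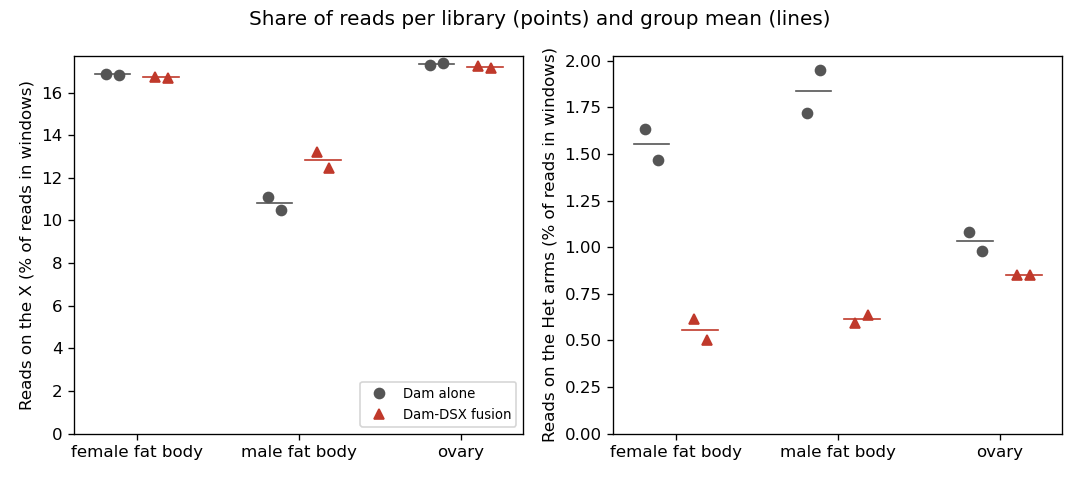
Percent of each library's reads that fell on the X (left) and on the Het arms (right), per tissue, with circles for Dam libraries, triangles for Dam-DSX fusion libraries and lines for the means of 2 libraries. Male fat body has the lowest X shares, with both fusion libraries (13.2% and 12.5%) above both Dam libraries (11.1% and 10.5%).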

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

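In this part the female tissue test was chosen only after the result was seen. The read ceiling and single-window tests were set before their results were seen.

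The ratio of fusion over Dam differed between the sexes in fat body in 34 windows by the direct test, a count that depends on how the libraries are paired. A difference can arise where a fusion falls below Dam, so it is not in itself a gain of occupancy. Female fat body and ovary differed in 14172 windows by the same test. Chromosome 4 moved in opposite directions in every library of female fat body and ovary. Relative to the autosomal arms its reads in the fusion changed by -0.25 in female fat body and 0.45 in ovary on the log2 scale, a difference of -0.70 that was not tested.

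The X also moved apart. Relative to autosomal reads, both male fusion libraries lay above both male Dam libraries, while both female fat body fusions lay below their Dam libraries. Both ovary fusions also lay below, but barely. Their log2 values of X over autosomes were -2.222 and -2.236, against -2.221 and -2.215 for ovary Dam, so the ovary direction may be noise. The log2 change was 0.25 in male fat body, -0.04 in female fat body and -0.01 in ovary. The female minus male difference was -0.29 and the male minus ovary difference 0.26, neither of them tested across libraries. A ceiling on reads per window, which would lift the weaker male X in deep windows, is argued against. With windows matched on female reads, the X offset of the fusion still exceeded that of Dam by 0.28 (bootstrap SD 0.03). A few windows with most of the reads are argued against too. The median over single windows with a mean of at least 10, X minus autosomes, gave a male minus female gap of 0.48 (SD 0.02). The filter was applied in each sex separately, so part of this gap can reflect unlike sets of windows. Over X windows that passed in both sexes, the median female minus male difference was smaller, at -0.33. On 2L, 2R, 3L and 3R that median lay between -0.01 and 0.05. Female tissue in both male fusion libraries stays open: 31.5% of it could account for the offset, and Y reads relative to Het reads fell to 12.8% in males. In female fat body they fell to 20.6%, with 168 Dam reads and 13 fusion reads, so the fall is not specific to males and cannot serve as a measure of female tissue. The sex of the flies and the form of DSX stay open as untested biological explanations.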

How the results depend on the processing

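Scaling by total reads, edgeR's interaction tests, the replicate block and the rebuilt ovary list were chosen after seeing the data. Of 87 alternatives other than leaving out a library, 49 stayed within 1.5 times of the main value and 38 did not. A stricter rule calls fewer by construction, and otherwise the cause was not tested. At an adjusted p of 0.01, lower windows numbered 16693 in female fat body, 10026 in male fat body and 22419 in ovary, higher windows 14760 in male fat body and 13372 in ovary, and differing windows 17 between the sexes and 6072 between female fat body and ovary. Under edgeR, lower windows in female fat body numbered 49571 and differing windows of female fat body and ovary 35385. With scaling by total reads, lower windows numbered 90990 in female and 58284 in male fat body, higher windows 17478 in male fat body, and differing windows 626 between the sexes and 43197 between female fat body and ovary. DESeq2 called 11130 lower windows in male fat body. Reciprocal overlap of 50% left 3607 female and 2890 male fat body peaks shared with ovary. Taking the 50% of peaks with larger folds left 2386 shared between the sexes, 2186 female and 2048 male fat body peaks shared with ovary, and 1292 regions of all 3 lists. The rebuilt ovary list gave 3359 and 2898 in place of the ovary overlaps of female and male fat body.

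Leaving out 1 library at a time in edgeR assumes that a lone library varies like the others, and is set against the deposited calls of another tool. Higher windows ranged from 0 to 42795 in female fat body, from 13670 to 29634 in male fat body and from 9190 to 28882 in ovary. Lower windows ranged from 0 to 38670, from 7537 to 27406 and from 2834 to 38292 in the same order. Differing windows ranged from 0 to 878 between the sexes and from 5508 to 41510 between female fat body and ovary. The counts of 0 for female fat body came without fusion library a and without fusion library b, while edgeR called 40415 and 42795 higher windows without Dam library a or b.

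The recovered libraries carry no replicate numbers, so which Dam library pairs with which fusion library is unknown, and edgeR was fitted with a replicate block for both pairings. Deviations of library a from b had an r between Dam and fusion of 0.657 in male fat body, 0.0973 in female fat body and 0.0867 in ovary, a hint from the data for a with a in males. Paired a with a, higher windows numbered 55418 in female and 54690 in male fat body and lower windows 57702 and 49321. Paired a with b, higher windows numbered 51718 and 12566 and lower windows 52584 and 6303. Ovary counts stayed within 1.5 times. With male libraries paired a with a, windows that differed between the sexes numbered 5723 or 3405 for female libraries paired a with a or a with b. With male libraries paired a with b they numbered 57 or 40. Between female fat body and ovary the 4 pairings gave 44971, 39813, 38138 and 33526. The count between the sexes thus depends on how the male libraries pair. Leaving out the dsx gene, and all alternatives for gene lists, the motif and peak positions, were not run, since a dm3 annotation or sequence was not used here. The least deep library was a male Dam library with 7727943 reads, and simulated 2-fold changes were not recovered by edgeR in female fat body or in the sex interaction. Few windows were changed in the simulation, so its female fat body recovery does not carry over to the counts within tissues.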

Other observations

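In this part both tests of the ovary list, the test of the sex of the male fusion libraries and the test counted in reads were chosen only after the result was seen, as was the count by chromosome arm. The median gap on windows with few Dam reads was set before.

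Of the 14 windows that were higher in the female than in the male fat body fusion, 10 were on 3L, from 1322001 to 10046001, where 19.9% of the compared windows lie. Of the 20 windows lower in females, 3 were on 3L. The arm was singled out from these counts, so no p is given. The male fusion held at most 3 reads over both libraries in 4 of the 14. Per the labels the transgenes sit on the same arm.

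Some peaks spanned several kilobases. At 3L the female peak from 19888001 to 19897500 and the male peak from 19888501 to 19896000 overlapped and had median log2 fold changes of 2.05 and 1.94. Peaks of at least 5 kb numbered 120 in female and 26 in male fat body, and 233 in the ovary list, which did not follow its own table. Reads of male fusion replicates varied 7.28 times as much as binomial sampling, against 3.66 times in females. Adjacent male windows may thus have passed less often, and a difference in peak length between the sexes was not tested.

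Y and heterochromatic sequences took a smaller share of reads in the fat body fusions than in Dam. Y reads in male fat body were 1982 and 1353 in the Dam libraries and 99 and 54 in the fusions. A lower ratio in all windows with few Dam reads was first tested by the median gap to arm windows with as many Dam reads. Its log2 value was -1.44 (bootstrap SD 0.10) in females, -1.58 in males and -2.26 in ovary, whose share of such reads fell least, so this gap does not follow the loss and decides nothing. Counted in reads, the log2 ratio of fusion over Dam in Y, Het and unplaced windows lay -1.64 from that of arm windows in females and -1.78 in males. Against arm windows with as many Dam reads it was -1.56 (SD 0.12) and -1.63 (SD 0.12). At least 91.7% of the fall (SD 0.892) was thus kept, so a lower ratio wherever Dam reads are few is argued against as the whole cause. The ovary values were -0.35 before matching and -0.64 after it. Male fusion libraries made wholly from female tissue are argued against, because the highest male value of log2 X over autosomes lay 0.40 below the lowest female one (-0.40). Why fat body and ovary differ stays open, with tissue as an untested biological explanation.

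The ovary peaks match a comparison that leaves out 1 Dam library. A looser limit on the same deposited p-values is argued against: the best limit misplaced windows equal to 39.1% of the peak windows, against 0% in both fat body lists. Dam library a alone against both fusion libraries, with a fold limit per coverage bin, misplaced 390 windows (1.33%). That was the lowest of 9 choices of libraries, tried after an earlier form of the test had shown the same choice as lowest, and the 5% bound was set after that, while all 4 libraries misplaced 7319 (25.0%). In fat body the choice of all 4 libraries was lowest, with 913 windows in females and 1109 in males. A candidate explanation is that the ovary peaks were called without Dam library b, although the labels describe peaks from both replicates. The overlaps above carry that limit, and the rebuilt list gave 2620 regions of all 3 lists in place of 3857. No biological explanation was tested.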
